A study of Mus musculus with 20 samples.

How the data were processed

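Messenger RNA of microglia, the resident macrophages of the brain, was sequenced from the frontal cortex of mice at postnatal day 40. Per the labels' protocols, 1000 cells per mouse were sorted by flow cytometry on high CD11b and low CD45, cDNA was made by template switching and amplified, and libraries were prepared with a Nextera kit. The 20 libraries carry 5 genotype labels: WT (n = 4), C4-/- (n = 5), hC4A/- (n = 5), hC4B/- (n = 4) and hC4A/A (n = 2). C4 is a component of the classical complement pathway, encoded in the mouse by C4b, and hC4A and hC4B denote the human C4A and C4B genes. Groups and replicate numbers were taken from the sample titles. Each library was treated as 1 mouse, as the protocol gives a cell number per mouse.

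The deposited files hold raw counts of reads per gene, in the layout that STAR writes when it counts reads over annotated genes. Per the submitters' processing notes, STAR, edgeR and the mouse build GRCm38 were used, and the tool versions and the annotation release are not given in the sources used here. The gene identifiers were looked up in GENCODE annotation of GRCm38, where 54809 of 54838 genes had a symbol. The count column that ignores strand was used: the 2 stranded columns split each library almost evenly, with 50.1% to 50.3% of their counts on one strand, so reads from overlapping antisense genes cannot be told apart. Summary lines for unmapped, multimapping, featureless and ambiguous reads stayed out of library sizes and tests. Over the 20 libraries these 4 classes took 14.8% to 42.1%, 13.2% to 28.9%, 21.8% to 42.1% and 0.897% to 5.86% of all reads. A series matrix named as normalized by the authors held 24057 genes, and all 481140 of its values equalled the raw counts of the deposited per-library files, so it served only to define an alternative gene set.

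The sum over genes ran from 855099 to 2735181 counts per library, with a median of 1710215.5. Gm10800, a predicted gene over satellite-like sequence (chromosome 2, 98666547 to 98667301), took 9.61% to 65.9% of those counts, and together with 12 further satellite-like genes 13.3% to 81.0%. The median detected gene held between 3 and 16 counts. Such counts come from amplified cDNA without molecular identifiers, so intervals and floors cover counting error only. Where a group held no count of a gene, folds were computed against a floor of 3 counts over the group and are lower bounds. Where it held 1 to 3 counts, the ratio is given with an exact 95% interval. Pairs of libraries within a genotype differed by 21.6 to 165 times the chi-square that sampling noise would give per degree of freedom, so no pair was made of copies of 1 library.

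Genes were filtered with filterByExpr by genotype, which kept 12680, and scaled by the TMM method. All 20 libraries entered 1 edgeR quasi-likelihood model (edgeR 4.0.16 in R 4.3.3, robust) with 1 coefficient per genotype and 15 residual degrees of freedom, without covariates. The common dispersion was 1.07, a biological coefficient of variation of 1.03. P values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene passed at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Group means are CPM scaled by the TMM factors, with the SD over libraries. Contrasts were each other genotype against WT, each genotype with human C4 against C4-/-, hC4A/- against hC4B/-, hC4A/A against hC4A/-, a trend over 0, 1 and 2 hC4A alleles, and an F test for any difference among the 4 genotypes other than WT. The trend over 3 group means weights hC4A/A against C4-/- only, so its p values equal those of that contrast. A contrast of the 4 other genotypes together against WT was added after the data were seen.

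Lists of genes numbered 25 and were written before the data were examined, as were the contrasts, the tests and a first set of other settings. They cover complement components and regulators, homeostatic microglia, disease-associated microglia, phagocytosis and lysosome, synapse pruning receptors and signals, the type I interferon response, antigen presentation, inflammatory cytokines and NF-kB, immediate early and dissociation genes, cell cycle, lipid and cholesterol metabolism, glycolysis, nuclear oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrial genome transcripts and sex-linked transcripts. Marker lists of other cells that the gate could let through cover border macrophages, monocytes, neutrophils, lymphocytes, neurons, astrocytes, oligodendrocytes, endothelial and mural cells, and erythroid cells. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusting over the 25 lists of a contrast. The score of a list is the mean log2 CPM of its tested members with a prior count of 2, compared between groups by two-sided exact permutation tests. Genes near C4b were counted within 10 Mb and compared with all other genes by Fisher's exact test.

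The genes named were C4b and C4a, then, where fewer than 5 genes passed in a contrast, those that passed and the 6 genes of smallest p. From 6 lists of microglial biology and from each list that passed camera, the members of smallest p with a mean log2 CPM of at least 3 were added. The rule allowed 2 to 4 members per list, and the number 2 was set after the values were seen. Ccl2 and Tubb5 were followed in every contrast with WT after their values were seen, and so were a few genes singled out below. A further gene is not reported here.

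Other settings fixed at that time were DESeq2 1.42.0, limma voom with quality weights, RLE scaling, no filter, a filter of at least 5 CPM in at least 4 libraries, fits on only the groups compared, a replicate block, 1 surrogate variable (sva 3.50.0), number series in the deposited sample names as a factor among the libraries other than WT, and each library left out in turn. Runs of close numbers in the names were taken as 1 series, and names without a plain number as 1 more. What the series stand for is not stated. Settings chosen after seeing the data left out the 4 libraries with over 27000 genes detected, left out the satellite-like genes, used the genes of the deposited matrix, or added 1 of 2 covariates, the summed CPM of 1733 olfactory and vomeronasal receptor genes or the balance of sex-linked transcripts. For the allele trend, the allele number as a numeric covariate was another such setting.

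The count tests were tested on simulated data with the means and dispersions of the real genes and the real library and group sizes, with changed genes drawn from those with a mean log2 CPM of at least 3. For C4-/- against WT, hC4A/- against C4-/- and hC4A/- against hC4B/-, edgeR recovered 6%, 5% and 0% of 100 genes changed 4-fold and 55%, 53% and 50% of 100 genes changed 16-fold. It made 2, 4 and 0 false calls among those of the 12680 genes that were left unchanged. DESeq2 recovered 13%, 19% and 16% of the 4-fold and 77%, 78% and 73% of the 16-fold changes, with 33, 22 and 32 false calls. Voom recovered 4%, 5% and 2%, and 50%, 57% and 53%, with 8, 8 and 6 false calls. The immediate early genes were also lowered 2-fold in the first group of each contrast. All libraries were drawn from the same gene means, so the libraries with over 27000 genes detected were not imitated. The simulated false calls therefore do not show how many calls are false where such libraries are compared. Sequences of the human C4 genes were not analysed here.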

Results

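Transcripts of sorted frontal cortex microglia were counted in 20 libraries, 1 per mouse, from mice at postnatal day 40. The labels name 4 WT mice, 5 mice lacking C4 (C4-/-), 5 carrying human C4A on 1 allele (hC4A/-), 4 carrying human C4B on 1 allele (hC4B/-) and 2 carrying human C4A on both alleles (hC4A/A). Median gene counts per library were 1719700 in WT, 1514541 in C4-/-, 1808031 in hC4A/-, 1726146 in hC4B/- and 1718365 in hC4A/A. The design asks what microglia change when mouse C4 is lost, when either human gene is added, and when the human C4A dose is raised.

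Mouse C4b (ENSMUSG00000073418, GRCm38 chromosome 17, 34728380 to 34743882) went against a plain reading of the labels WT and C4-/-. It held 0, 0, 2 and 0 counts in the 4 WT libraries, and between 4 and 428 counts in each of the 16 libraries of the other genotypes. Mean C4b was 0.383 ± 0.767 CPM in WT (SD, n = 4), 40.7 ± 41.4 in libraries labelled C4-/- (n = 5), 9.46 ± 5.94 in hC4A/- (n = 5), 144 ± 162 in hC4B/- (n = 4) and 179 ± 244 in hC4A/A (n = 2). C4a (ENSMUSG00000015451, chromosome 17, 34809092 to 34823464), the near-identical neighbouring copy, held 2, 5, 1, 17 and 9 counts over the same groups. Reads aligned to both copies count as multimapping and stayed out, so C4b may be undercounted in every library. The part of C4b deleted is not stated in the labels, and counts per gene do not show which exons the reads came from. Genotype names below are therefore those of the labels, and directions drawn from them rest on labels that C4b did not bear out. C4b separated WT from all other labels, but the counts do not show whether any label is right or wrong. The genotype names with human C4 do not mention mouse C4.

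**Figure D1:**
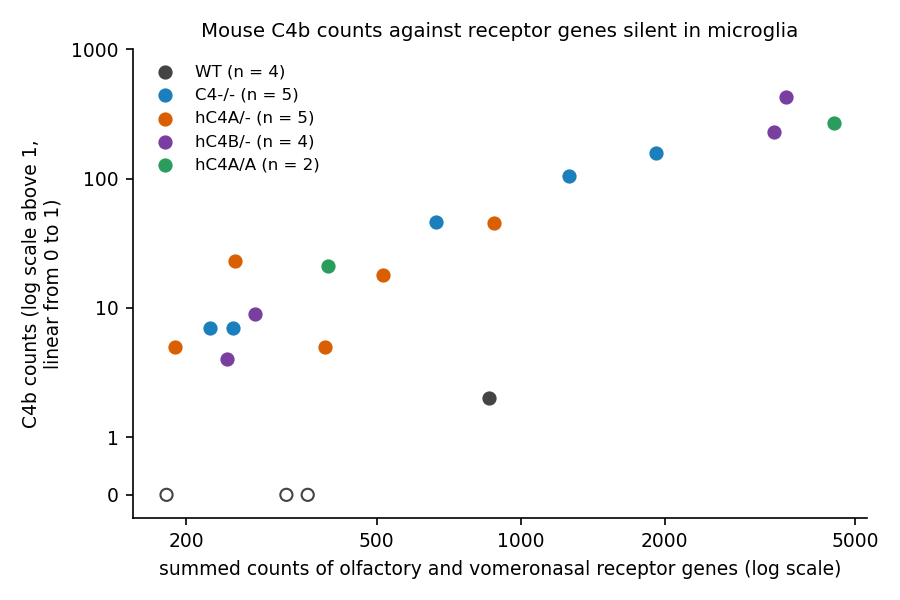
C4b counts of each library (y axis, log scale above 1 and linear from 0 to 1) are plotted against the counts summed over olfactory and vomeronasal receptor genes (x axis, log scale), with colours for genotype labels and open circles for 0 counts. All 16 libraries of the other genotypes lie above the 4 WT libraries.

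Olfactory and vomeronasal receptor genes, silent in microglia, were detected broadly in 4 libraries that also held over 27000 detected genes. These broad libraries were C4-/- replicate 3, hC4B/- replicates 2 and 3, and hC4A/A replicate 2, with 27178, 30041, 30176 and 30907 genes, against 11348 to 23912 in the other 16. Of the 1733 receptor genes, 50.7% to 67.2% were detected in the broad libraries and 5.37% to 35.5% in the others. Spearman correlations of log2 CPM across genes had a median of 0.725 over the 120 pairs of other libraries and of 0.448 over the 64 pairs of a broad and another library. Genes are not independent replicates in these correlations. The median log2 fold change of all genes was 0.33, -0.05, 0.18 and 0.18 for C4-/-, hC4A/-, hC4B/- and hC4A/A against WT, and 0.39, -0.03, 0.53 and 0.48 with RLE scaling. Single-gene changes near those sizes are shifts of all genes, and camera compares each list with the other genes.

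**Figure D2:**
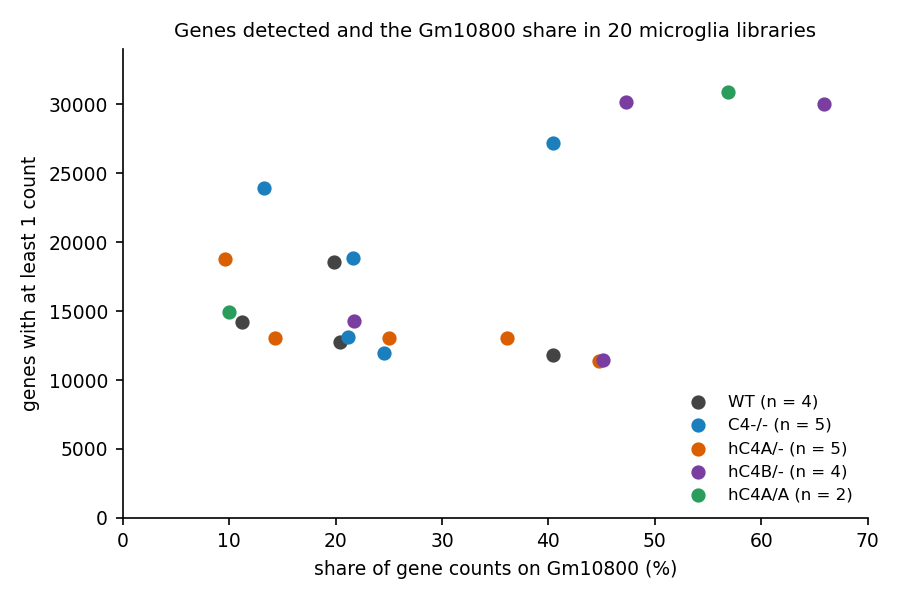
Genes with at least 1 count (y axis) are plotted against the percent of gene counts on Gm10800 (x axis) for each of the 20 libraries, with colours for genotype labels. The 4 broad libraries hold 27178 to 30907 detected genes and the other 16 hold 11348 to 23912.

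In libraries labelled C4-/- against WT, microglia held less of the chemokine Ccl2 and of the tubulin Tubb5. Ccl2 averaged 15.9 ± 12.4 CPM in C4-/- (SD, n = 5) and 200 ± 64.8 in WT (n = 4), a log2 fold change of -3.64 ± 0.89 (SE). Tubb5 averaged 239 ± 171 CPM against 1302 ± 720 (log2 fold change -2.45 ± 0.79). The activation genes Fosl2 (45.3 ± 30.6 against 158 ± 109 CPM) and Rgs1 (8.84 ± 4.78 against 47.9 ± 39.8) were lower too, while the homeostatic genes Golm1 (173 ± 61.2 against 75.7 ± 37.6) and Selplg (489 ± 245 against 214 ± 85.2) were higher. Leaving out WT replicate 3 moved the log2 fold change of Fosl2 from -1.80 to -1.22 and that of Rgs1 from -2.42 to -1.72. Selplg went from 1.19 to 0.69 without the broad C4-/- replicate 3, and the homeostatic score did not differ (difference 0.17, exact permutation p = 0.492). None of these passed: edgeR called 0 of 12680 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.529 and 1084 genes under an unadjusted p of 0.05, where chance gives 634. DESeq2 called 20 genes and voom 0, and among the DESeq2 calls were C4b and Ccl2 (adjusted p = 0.0160 each) and Tubb5 (0.0379). Over the other settings the adjusted p ran from 0.016 to 0.69 for Ccl2 and from 0.038 to 0.80 for Tubb5. C4b was higher by 6.85 ± 1.59 on the log2 scale, a ratio of 170 in counts scaled to library size (95% interval 46.7 to 1411), and by 5.83 without the broad C4-/- replicate 3. Such intervals, and the folds given as at least, cover counting error only here and below, not the spread between mice. The 6 genes of smallest p included Nacad, at least 59.7-fold higher, Zfp97, at least 25.1-fold lower (log2 fold change -5.56 in place of -7.61 without WT replicate 2), Spaca6 (log2 fold change 6.65 ± 1.67) and 3110056K07Rik (4.88 ± 1.20, and 4.07 without C4-/- replicate 1).

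Among lists in the same contrast, immediate early and dissociation genes were lower (22 of 33 tested genes below 0, median log2 fold change -0.46, camera adjusted p = 6.5e-04, but 0.21 with an estimated correlation). Neutrophil markers were lower as well (7 of 8 below 0, median -3.74, adjusted p = 1.6e-09, but 0.178 with an estimated correlation). Lcn2 averaged 2.55 ± 5.34 CPM against 47.4 ± 61.8 in WT, and Ngp 1.74 ± 3.54 against 40.6 ± 68.9. WT replicate 2 held 140 CPM of Lcn2 and 144 of Ngp, the other WT libraries at most 23 and 9.35, and without it the log2 fold changes were -2.65 and -1.75. Adjusted over the list alone, 10 genes passed, namely C4b, Cd46 and Ccl2 and 7 neutrophil genes, against 0 adjusted over all genes. Cd46, a complement regulator, averaged 18.7 ± 35.3 CPM against 0.471 ± 0.352, a ratio of 59.4 (95% interval 20 to 291, counting error only). This rests on C4-/- replicate 4, with 81.6 CPM against 0 to 5.59 in the other 4, and without it the log2 fold change was 2.60.

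In hC4A/- libraries against WT, Ccl2 averaged 28.7 ± 30.3 CPM (SD, n = 5) against 200 ± 64.8 (n = 4), a log2 fold change of -2.80 ± 0.86 (edgeR adjusted p = 0.422). Tubb5 averaged 194 ± 33.6 CPM against 1302 ± 720 (-2.75 ± 0.79, adjusted p = 0.404). The immediate early genes Fos (8.58 ± 5.88 against 52.2 ± 40.6 CPM, log2 fold change -2.59 ± 0.94) and Klf4 (2.59 ± 5.41 against 25.2 ± 8.27, -3.17 ± 1.29) were lower, with Fos at -1.97 without WT replicate 2. edgeR called 0 genes, with 952 under an unadjusted p of 0.05. DESeq2 called 21 and voom 6, and fits without the broad libraries called Tubb5 (adjusted p = 0.0052, log2 fold change -2.60). C4b was higher by 4.75 ± 1.52 on the log2 scale (ratio 41.6, 95% interval 11.2 to 349, counting error only). Rbm19 was lower by a log2 fold change of -5.89 ± 1.35 (-4.63 without WT replicate 3). Nacad was at least 77.2-fold higher (log2 fold change 7.56 in place of 8.36 without hC4A/- replicate 5). Immediate early genes as a list were lower (26 of 33 below 0, median -0.62, camera adjusted p = 4.9e-05), ribosomal protein genes higher (65 of 72 above 0, median 0.43, 6.7e-04) and neutrophil markers lower (7 of 8 below 0, median -2.97, 1.0e-05). With an estimated correlation the adjusted p was 0.178, 0.938 and 0.380. The ribosomal difference rested on single libraries, with an adjusted p of 0.128 without WT replicate 2 and 0.436 without hC4A/- replicate 5. Neutrophil markers gave 0.0395 without WT replicate 2, with Camp at -1.13 in place of -2.93 and S100a8 at -1.68 in place of -3.06. Mx1, Mmp8 and Pecam1, 3 genes and all lower, passed adjusted over the list alone, against 0 adjusted over all genes.

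In hC4B/- libraries against WT, Ccl2 averaged 3.56 ± 2.97 CPM (SD, n = 4) against 200 ± 64.8 (n = 4), a log2 fold change of -5.73 ± 1.09 and the closest approach to the threshold by a named gene in this contrast together with C4b (edgeR adjusted p = 0.0917 for both). C4b was higher by 8.66 ± 1.69 on the log2 scale (ratio 456, 95% interval 126 to 3773, counting error only). But hC4B/- replicates 2 and 3, both broad, held 230 and 428 of its 671 counts. Without the broad libraries the log2 fold change of C4b was 3.50 (adjusted p = 0.757), a fold below that interval. Tubb5 averaged 119 ± 102 CPM (log2 fold change -3.45 ± 0.89), Atf3 0.943 ± 1.17 against 37.7 ± 40.4 and Rgs1 7.04 ± 4 against 47.9 ± 39.8 (log2 fold change -2.76, and -2.06 without WT replicate 3). edgeR called 0 genes, with 1658 under an unadjusted p of 0.05. DESeq2 called 53, among them C4b (adjusted p = 1.0e-04), Ccl2 (6.9e-06) and Tubb5 (0.0014), and voom called 1142, of which 697 were higher and 445 lower. Leaving out hC4B/- replicate 1 or 4 gave 1 gene by edgeR, and leaving out hC4A/A replicate 1 or 2 gave 2. Over the other settings the adjusted p ran from 6.9e-06 to 0.57 for Ccl2 and from 1.5e-06 to 0.76 for C4b. Elavl3 was at least 176-fold higher, a bound for counting error only, with a log2 fold change of 5.87 in place of 9.25 without hC4B/- replicate 1. Jak3 averaged 435 ± 852 CPM against 2.59 ± 1.92, but its log2 fold change went from 7.40 to 1.94 without hC4B/- replicate 3 and reversed to -1.38 without the broad libraries.

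Lists lower in hC4B/- than in WT were inflammatory cytokines and NF-kB (20 of 26 below 0, median -0.66, camera adjusted p = 0.0020), immediate early genes (23 of 33, median -0.69, 0.0013) and neutrophil markers (7 of 8, median -3.04, 0.0020). Their adjusted p was 0.232, 0.232 and 0.626 with an estimated correlation. The neutrophil difference rested on single libraries, with 0.208 without WT replicate 2 and 0.189 without hC4B/- replicate 1, and the NF-kB list gave 0.105 without the broad libraries. C4b, Ccl2, Eif2s3y, Il7r and Cspg4, 5 genes, passed adjusted over the list alone, against 0 adjusted over all genes. Eif2s3y is Y-linked, and its call cannot be told apart from the sex of the mice, which the labels do not give. Sex-linked scores were 1.37 to 2.61 in hC4B/- but reached 4.90 in WT, and a difference in sex would bear on every gene of this contrast. With the sex-linked covariate edgeR called 0 genes, with 1627 under an unadjusted p of 0.05. Of 261 tested genes within 10 Mb of C4b, C4b and C4a left out, 0 passed at an adjusted p under 0.05. At an unadjusted p under 0.05, a criterion chosen after the results were seen, 46 (17.6%) did, against 1611 of 12417 others (13%). The Fisher exact p was 0.0325, adjusted over contrasts 0.357. Fisher's test takes genes as independent, which genes measured in the same libraries are not.

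In hC4A/A libraries against WT, the 2 libraries held 43.4 ± 52.2 CPM of Ccl2 (SD, n = 2), a log2 fold change of -2.18 ± 1.20, and 104 ± 116 CPM of Tubb5 (-3.64 ± 1.21). Without the broad replicate 2 these were -1.28 and -2.74. The antigen presentation gene Psmb9 averaged 5.65 ± 0.667 CPM against 58.3 ± 60.8, Ccl4 1.62 ± 0.452 against 15.6 ± 7.99, and Junb 15.7 ± 3.48 against 67.9 ± 67.1. Leaving out WT replicate 3 moved the log2 fold change of Psmb9 from -3.33 to -2.32 and that of Junb from -2.12 to -1.18. C4b was higher by 8.97 ± 1.76 on the log2 scale (edgeR adjusted p = 0.201), a ratio of 308 (95% interval 84.5 to 2554, counting error only). It held 351 CPM in the broad replicate 2 and 6.77 in replicate 1. Without the broad libraries the log2 fold change of C4b was 4.34, a fold below that interval. edgeR called 0 genes, with 1066 under an unadjusted p of 0.05, DESeq2 called 4 (C4b, Tubb5, Nacad and Gm31305) and voom 0. Without hC4A/A replicate 1 edgeR called 1. Antigen presentation (10 of 16 below 0, camera adjusted p = 0.018), inflammatory cytokines and NF-kB (18 of 26, 0.018), immediate early genes (23 of 33, 0.010), oxidative phosphorylation (53 of 71, 3.9e-04) and ribosomal protein genes (68 of 72, 8.5e-10) were lower as lists. With an estimated correlation the adjusted p was 0.598 to 0.613. Without hC4A/A replicate 2, a broad library, it was 0.939 to 0.943 for the 5 lists, and the direction of oxidative phosphorylation and ribosomal protein genes reversed, as it did without the 4 broad libraries (0.966 and 0.948). Adjusted over the list alone, Cd46, C4b and Cspg4 passed, 3 in all, against 0 adjusted over all genes.

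**Figure D3:**
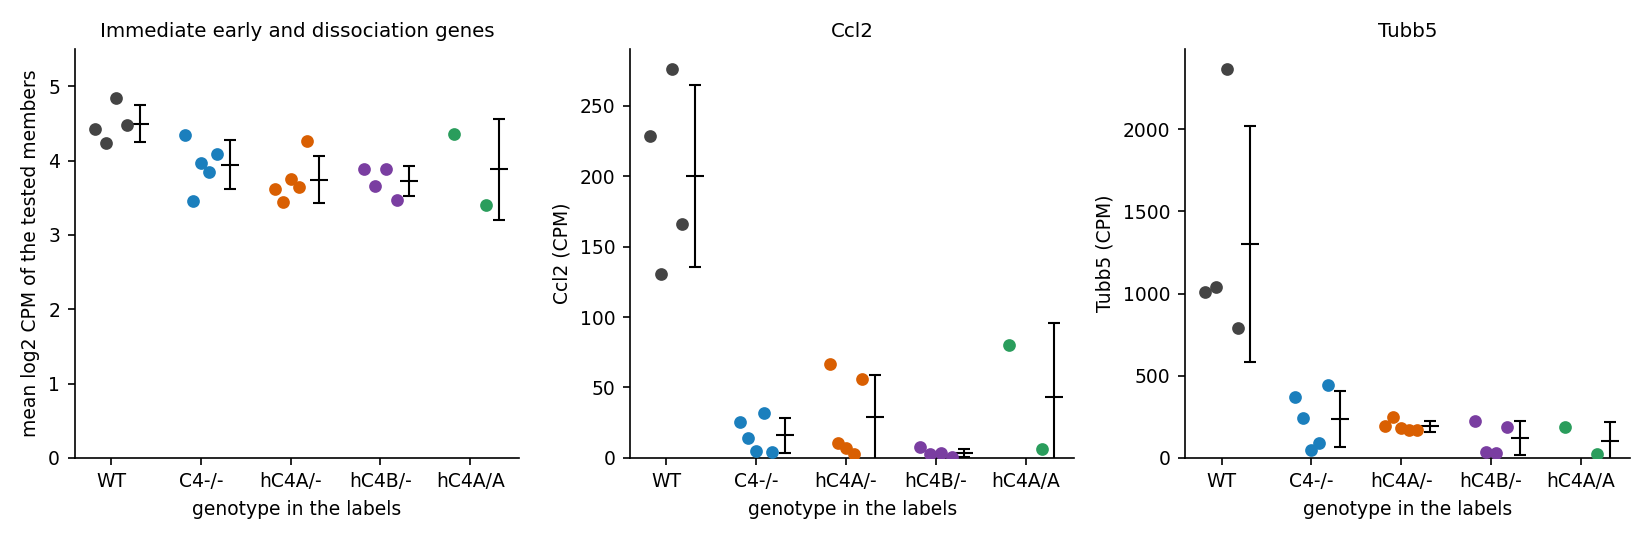
The immediate early score (mean log2 CPM) and the CPM of Ccl2 and Tubb5 are plotted for each library by genotype label, with points for libraries and bars for the mean ± SD, ending at 0 in the CPM panels. The 4 WT libraries lie above all 16 others for Ccl2 (130 CPM or more against 80.3 or less) and for Tubb5 (791 or more against 442 or less).

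Taken as 1 group of 16, the other genotypes held 20.2 ± 25.4 CPM of Ccl2 and 178 ± 118 CPM of Tubb5, against 200 ± 64.8 and 1302 ± 720 in WT. This contrast was chosen after the values were seen. The log2 fold changes were -3.59 ± 0.65 and -3.07 ± 0.59, each with an edgeR adjusted p of 0.0545, so no gene passed, with 1218 under an unadjusted p of 0.05. Rgs1 averaged 9.9 ± 9.4 CPM against 47.9 ± 39.8, and Nfkbid 5.79 ± 6.02 against 37.6 ± 19, and both passed adjusted over the list alone (0.0217 and 0.0283). In all 14 genes passed that way, against 0 adjusted over all genes, the others being C4b, Ccl2, Tap1, Cspg4, Pecam1 and 7 neutrophil genes. That adjustment is within each list and not over the 25 lists. Without WT replicate 3, the log2 fold change of Tap1 in hC4A/A against WT went from -3.29 to -0.34. That of Ccl2 in C4-/- against WT was still -3.39 in its weakest fit. The neutrophil score was 6.95 in WT replicate 2 and 3.40 to 3.98 in the other WT libraries. The immediate early score averaged 4.50 ± 0.25 in WT, 3.94 ± 0.33 in C4-/-, 3.74 ± 0.31 in hC4A/-, 3.72 ± 0.20 in hC4B/- and 3.88 ± 0.68 in hC4A/A. It was lower by a difference of -0.68 in the 16 libraries than in WT (two-sided exact permutation p = 0.00103, adjusted over 25 lists 0.0258). Without the broad libraries the adjusted p was 0.0755, and camera with an estimated correlation gave 0.109, so the difference passed in only some tests. Neutrophil markers moved with it (score difference -2.27, exact permutation p = 0.00557, adjusted over 25 lists 0.0697). All 4 WT libraries, and no others, had deposited names without a plain number and were placed in a series of their own. Genotype and series therefore cannot be told apart in any contrast with WT.

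In hC4A/- libraries against those labelled C4-/-, Usp18 (22.1 ± 9 CPM, n = 5, against 4.91 ± 5.75, n = 5) and Fosl2 (187 ± 71.7 against 45.3 ± 30.6) were higher. Ifi204 averaged 31.9 ± 64.1 CPM against 1.06 ± 1.13, but hC4A/- replicate 5 held 146 CPM and the other 4 held 0 to 11.7, and without it the log2 fold change was 1.58 in place of 4.84. The interferon list did not differ (score 2.82 ± 0.48 against 2.92 ± 0.46, exact permutation p = 0.762, camera adjusted p = 0.958). Rhob (38.5 ± 8.16 against 143 ± 113 CPM), Tgfbr2 (17.4 ± 8.13 against 69.2 ± 82.6), Lamp1 (22.4 ± 10.4 against 59.6 ± 44.2) and Psap (68.7 ± 25.5 against 238 ± 256) were lower, and without the broad C4-/- replicate 3 their log2 fold changes went from -1.89, -1.98, -1.40 and -1.79 to -0.98, -0.55, -0.60 and -0.55. edgeR called 0 genes, with a smallest adjusted p of 0.416 and 1354 genes under an unadjusted p of 0.05. DESeq2 called 10 and voom 1, Zfp383, which averaged 56.8 ± 26.7 CPM against 1.06 ± 1.53 (log2 fold change 5.65 ± 1.37). Sec24b (-4.39 ± 0.99, and -3.57 without C4-/- replicate 3), Mcm3 (-4.21 ± 1.07) and Hs3st3b1 (4.04 ± 1.02) were also among the genes of smallest p. C4b was lower by a log2 fold change of -2.09 ± 1.06 (adjusted p = 0.477), and by -0.96 without C4-/- replicate 3. Adjusted over the list alone, 4 genes passed, Ifi204, Mcm3, Hbb-bs and Hba-a1, against 0 adjusted over all genes. No list passed camera, and the smallest adjusted p was 0.182.

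In hC4B/- libraries against those labelled C4-/-, the homeostatic gene Gpr34 averaged 622 ± 429 CPM (n = 4) against 271 ± 135 (n = 5). Atf3 was lower, at 0.943 ± 1.17 against 21.2 ± 43.4 CPM, with a log2 fold change of -1.08 in place of -4.61 without C4-/- replicate 4. The genes of smallest p, Rbm27 (1207 ± 2359 against 26.6 ± 9.98 CPM), Cep83 (426 ± 834 against 9.12 ± 5.62), Mocs2 (357 ± 700 against 8.35 ± 9.1), Shisa5 (319 ± 586 against 11.4 ± 5.08) and Fam117a (470 ± 934 against 1.62 ± 2.09), rest in large part on hC4B/- replicate 3, a broad library. Without it their log2 fold changes, 4.80 to 8.14 with all libraries, were 0.24, 0.19, -0.24, 1.34 and 0.73, and Cep83, Mocs2 and Fam117a also reversed without the 4 broad libraries. edgeR called 0 genes (smallest adjusted p = 0.443), with 573 under an unadjusted p of 0.05. DESeq2 called 3 (Rnf181, Trim5 and Ddx3y) and voom 0. The log2 fold change of C4b was 1.81 ± 1.08 (adjusted p = 0.99) and reversed to -2.35 without the broad libraries, -0.68 with 1 surrogate variable and -0.30 with the receptor covariate, so its direction is not settled. Adjusted over the list alone, 5 genes passed, among them Bnip3, Kdm5d, Eif2s3y and Il7r, against 0 adjusted over all genes. Kdm5d, Eif2s3y and Ddx3y are Y-linked, and sex-linked scores were 1.37 to 2.61 in hC4B/- but reached 4.93 in C4-/-, so these calls cannot be told apart from the sex of the mice. A difference in sex would bear on the other genes of this contrast too. All 4 hC4B/- libraries lie in a number series with 1 of 5 C4-/- libraries. With series as a factor among the 16 libraries other than WT, 434 genes were under an unadjusted p of 0.05. No list passed camera, and the smallest adjusted p was 0.104.

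Dose of human C4A was addressed by hC4A/A libraries against those labelled C4-/- and hC4A/-. Against C4-/-, ribosomal protein genes were lower (69 of 72 below 0, median log2 fold change -1.14, camera adjusted p = 1.1e-18, but 0.617 with an estimated correlation), with Rpl8 at -2.16 ± 1.15, and at -0.91 without C4-/- replicate 5. Oxidative phosphorylation genes (61 of 71, median -0.85, 5.9e-06) and homeostatic genes (26 of 28, median -0.32, 0.0099) were lower and neutrophil markers higher (7 of 8 above 0, median 1.15, 3.8e-04). With an estimated correlation the adjusted p of these 3 was 0.617 as well. Without hC4A/A replicate 2 it was 0.903 for ribosomal, oxidative phosphorylation and homeostatic genes, all 3 with the direction reversed, and 0.294 for neutrophil markers, and without C4-/- replicate 3 it was 0.0516 for homeostatic genes, which also reversed without the 4 broad libraries (0.851). edgeR called 0 genes, with 275 under an unadjusted p of 0.05, DESeq2 1 (Gm31305) and voom 0. The log2 fold change of C4b was 2.13 ± 1.25, with 271 of 292 counts in the broad replicate 2, and it reversed to -1.51 without the broad libraries, -0.092 with 1 surrogate variable and -0.16 with the receptor covariate. Per allele over 0, 1 and 2 copies, the trend gave the same p values, with 0 genes by edgeR, 1 by DESeq2 and 0 by voom.

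Against hC4A/-, hC4A/A held lower ribosomal protein genes (71 of 72 below 0, median -1.10, camera adjusted p = 4.9e-18) and oxidative phosphorylation genes (63 of 71, median -0.81, 4.1e-07), with Rps2 at 7.43 ± 1.35 CPM (n = 2) against 30.7 ± 13.8 (n = 5). The adjusted p was 0.736 for both with an estimated correlation, and 0.664 and 0.727 without hC4A/A replicate 2. edgeR called 0 genes, with 1455 under an unadjusted p of 0.05, DESeq2 2 (Gm31305 and Arap2) and voom 0. Arap2 averaged 32.4 ± 20.2 CPM against 0.625 ± 0.618 (log2 fold change 5.47 ± 1.17, edgeR adjusted p = 0.36, and 4.63 without hC4A/A replicate 1). C4b and Vcan, 2 genes, passed adjusted over the list alone, against 0 adjusted over all genes, but C4b reversed to -0.48 without the broad libraries. Both dose contrasts rest on hC4A/A replicates of which 1 is broad.

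Between the human genes, hC4A/- libraries held less Rhob (38.5 ± 8.16 CPM, n = 5, against 229 ± 250, n = 4), less Gas6 (10.8 ± 8.1 against 47 ± 14.9) and more Lipa (67.3 ± 13.1 against 19.4 ± 5.47) and C5ar1 (192 ± 58.5 against 65.3 ± 56.8) than hC4B/- libraries. Sec24b averaged 1.31 ± 0.863 CPM against 46.5 ± 16, a log2 fold change of -5.03 ± 1.03 (edgeR adjusted p = 0.146). Bag6 (3.55 ± 2.27 against 626 ± 1211 CPM), Aloxe3 (0.43 ± 0.271 against 119 ± 234) and Zmiz2 (5.89 ± 6.39 against 406 ± 774) rest in large part on hC4B/- replicate 3. Without it their log2 fold changes went from -7.41, -7.89 and -6.07 to -2.57, -1.60 and -1.68, and that of Rhob from -2.57 to -1.62. Aloxe3 and Zmiz2 reversed to 3.00 and 0.87 without the broad libraries. edgeR called 0 genes, with 2122 under an unadjusted p of 0.05, DESeq2 58 and voom 1930 (619 higher, 1311 lower). Without hC4B/- replicate 1 edgeR called 8 genes, and without hC4B/- replicate 4 it called 5. Ribosomal protein genes were higher as a list (52 of 72 above 0, median 0.29, camera adjusted p = 0.0088), with an adjusted p of 0.928 with an estimated correlation, 0.913 without hC4B/- replicate 2 and 0.486 without hC4A/- replicate 5. Its direction reversed in the fit without hC4B/- replicate 2, with 1 surrogate variable (adjusted p = 0.00651, lower), without the broad libraries (0.856) and with the receptor covariate (0.995), so it is not settled. The log2 fold change of C4b was -3.91 ± 1.16 and reversed to 1.32 without the broad libraries, 0.57 with 1 surrogate variable and 0.21 with the receptor covariate. The genes that passed adjusted over the list alone were 6, C4b, Bnip3, Kdm5d, Eif2s3y, Il7r and Cspg4, against 0 adjusted over all genes. The calls of the Y-linked Kdm5d and Eif2s3y cannot be told apart from sex, as sex-linked scores reached 4.79 in hC4A/- and 2.61 in hC4B/-. A difference in sex would bear on the other genes too, and with the sex-linked covariate 2236 genes were under an unadjusted p of 0.05. The number series of all 4 hC4B/- libraries holds 1 of 5 hC4A/- libraries, so genotype and series are in large part mixed. With series as a factor among the 16 libraries other than WT, the count under an unadjusted p of 0.05 was 906 in place of 2122. That fit also left out WT, and the count fell to 1165 with a replicate block and 839 with 1 surrogate variable. The fall therefore does not show an effect of series. Across the 4 genotypes other than WT, the F test of edgeR gave 0 genes with 1053 under an unadjusted p of 0.05, DESeq2 9 and voom 0. Leaving out WT replicates 2, 3 or 4 gave 5, 4 and 5 genes, leaving out hC4B/- replicates 1, 2 or 4 gave 13, 16 and 19, and leaving out hC4A/A replicates 1 or 2 gave 3 and 2. In the fit of all libraries the smallest adjusted p (0.0512) was shared by Bag6, Rbm27, Cep83 and Aloxe3.

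Of the 25 lists, 7 passed camera in at least 1 of the 9 pairwise contrasts and 18 in none. The smallest adjusted p over the 9 contrasts was 0.32 for complement components and regulators, 0.114 for disease-associated microglia, 0.0531 for phagocytosis and lysosome, 0.138 for synapse pruning receptors and signals, and 0.415 for the type I interferon response. It was 0.199 for cell cycle, 0.142 for lipid and cholesterol metabolism, 0.337 for glycolysis, 0.142 for mitochondrial genome transcripts and 0.347 for sex-linked transcripts. The sex-linked list joins Xist with Y-linked genes, so a test of a shared direction can miss a difference in sex. Among markers of other cells it was 0.584 for border macrophages, 0.609 for monocytes, 0.198 for lymphocytes, 0.182 for neurons, 0.527 for astrocytes, 0.593 for oligodendrocytes, 0.389 for endothelial and mural cells and 0.237 for erythroid cells. The markers tested, in that order, were 2 of 10, 4 of 10, 2 of 15, 5 of 14, 5 of 12, 6 of 14, 7 of 13 and 2 of 7. Lists this short can hardly show a difference, so these values do not exclude other cells. Of the 225 pairs of list and contrast, 20 passed at the preset correlation and 0 with an estimated correlation.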

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

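All tests of explanations in this part were chosen only after the patterns were seen, and the tests of human C4 reads, of DNA bearing C4b, of carried-over genomic DNA and of blood cells in WT had their bounds or parts revised after their outcomes were known.

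Mouse C4b, the gene that the label C4-/- names as lost, held counts in all 16 libraries of the other genotypes and 2 counts in WT. An even background of genomic DNA does not account for it, since C4b lay at least 12.7 times above olfactory and vomeronasal receptor genes per kb of exon in each of the 16 libraries. Reads of human C4 are argued against in the libraries labelled C4-/- only if the labels hold, as these name no human gene and all 5 held more C4b than any WT library. As C4b did not bear out a plain reading of the labels, such reads stay open there. In the 11 libraries labelled with human C4 they stay open too, as C4b per 100 receptor counts differed from that of C4-/- libraries by -0.32 on the log2 scale (exact permutation p = 0.533). DNA bearing C4b that came with the genomic background may be a source. Over the 12 libraries other than WT and the broad ones, C4b followed receptor CPM (Spearman rho = 0.601, permutation p = 0.0433, adjusted over 2 relations 0.0866). Pearson r was 0.821 (permutation p = 0.00127, adjusted 0.00254). Without the 2 farthest libraries r was 0.519 (permutation p = 0.123), a weaker relation that did not pass. Across all 16 libraries, the broad ones included, C4b CPM spanned 131-fold and C4b per 100 receptor counts 9.34-fold. With the receptor covariate, C4b lay above WT by log2 fold changes of 5.27 in C4-/-, 5.17 in hC4A/-, 4.96 in hC4B/- and 5.11 in hC4A/A. These values go with such a source but do not show that the reads came from DNA. Whether a disrupted C4b or a swap of labels lies behind the counts was not tested.

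The 4 libraries with over 27000 detected genes stood apart from the other 16. Greater depth of counts outside satellite-like genes is argued against, because their median was 429090 against 1094899 in the others. In total reads, hC4B/- replicates 2 and 3 held 9870131 and 12952750, above the median of 8173116 over all libraries. C4-/- replicate 3 and hC4A/A replicate 2 held 7311979 and 7559514, below it, so total reads do not set the 4 apart. Genotype alone is argued against too, since 3 genotypes held libraries of both kinds. Carried-over genomic DNA is a candidate explanation for hC4B/- replicates 2 and 3 and hC4A/A replicate 2, where at least 77.6% of uniquely aligned reads outside satellite-like genes lay on no annotated exon, against 59.7% to 72.1% in the other 16. The first form of that test covered all 4 libraries and failed for C4-/- replicate 3, which had 67.2% off exons but 50.7% of receptor genes detected, so the test was then given by part and the explanation stays open for that library.

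Immediate early genes as a list were lower in the other genotypes than in WT, by score (difference -0.68, exact permutation p = 0.00103) but not by camera with an estimated correlation (adjusted p = 0.109), and Rgs1 alone passed adjusted over the list (0.0217, and 0.203 over all genes). The broad libraries are argued against as the cause, since the score difference without them was -0.652 (exact permutation p = 0.00385, adjusted over 25 lists 0.0755). Blood cells in WT stay open: without WT replicate 2, of the highest neutrophil score, the difference was -0.768 (exact permutation p = 0.00103), while the neutrophil score still differed by -1.47 (p = 0.0485), with S100a8 at 243 CPM in WT replicate 2 and 27.7 to 36.8 in the others, and a gate on low CD45 should remove neutrophils. Separate handling of the WT mice could also be the source, as 0 libraries of other genotypes share the WT number series and these genes respond to dissociation. Loss or replacement of mouse C4 is the biological explanation, but it was not tested, it rests on labels that C4b did not bear out, and it cannot be told apart from handling in this design.

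Single libraries lay far from the rest of their group in 14 of 140 groups of values, where a rate of 1 in 20 gives 7. That rate assumes normal and independent values. Some lists share members, Ccl2 and Tubb5 were picked after their values were seen, and the erythroid and WT C4b flags arose because the rest of the group held no counts. The excess over 7 is therefore no measure of outlying libraries. WT replicate 1 held 2412018 gene counts, hC4A/- replicate 5 had 18753 genes detected and hC4B/- replicate 4 had 97.2% of counts in protein-coding genes. List scores stood out for the type I interferon response in hC4A/- replicate 5 (3.66), lipid metabolism in WT replicate 3 (5.46), neutrophils in WT replicate 2 (6.95, others 3.40 to 3.98), neurons in C4-/- replicate 4 (0.69, the lowest) and oligodendrocytes in WT replicate 3 (2.88). Erythroid scores were high in WT replicate 2 (3.07), C4-/- replicate 5 (0.52) and hC4B/- replicate 4 (3.42), where the rest of each group had no counts of the 2 tested genes. WT replicate 3 held the WT counts of C4b (1.53 CPM) and the most Tubb5 (2369 CPM), and hC4A/- replicate 2 held 251 CPM of Tubb5. Among read classes outside the gene counts, the highest shares were 42.1% unmapped in hC4B/- replicate 3 (6 libraries above all WT), 28.9% multimapping in hC4B/- replicate 4 (2 above), 42.1% without a feature in hC4A/- replicate 5 (4 above) and 5.86% ambiguous in C4-/- replicate 3 (4 above).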

How the results depend on the processing

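Tests without the 4 broad libraries, without satellite-like genes, with the genes of the deposited matrix, with receptor or sex-linked covariates, with a numeric trend and with an unadjusted criterion near C4b were chosen only after the results were seen. Of the list results, 473 values under settings fixed beforehand and 81 under added ones kept direction and side of the threshold, 27 and 14 lost the threshold, and 7 and 5 reversed. Of the values for named genes, 4007 and 664 kept both, 107 and 45 passed where edgeR had not, and 16 and 16 reversed. As no gene passed in the main fit, the values that kept both had the same sign and again did not pass. Their size could still fall, as for Cep83 in hC4B/- vs C4-/-, from 5.54 to 0.19 without hC4B/- replicate 3. The tally also counts fits without a library of neither group compared, so it is no measure of robustness. A fit of normalized deposited values, chosen beforehand, was not run, because that matrix holds the same raw counts. The cause was not tested for any difference below, except that dropping a filter changes the genes tested and leaving out libraries leaves fewer samples. Counts of genes are those at an adjusted p under 0.05, and edgeR gave 0 in every contrast with the settings of the report.

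DESeq2 called 20 genes for C4-/- vs WT, 21 for hC4A/- vs WT, 53 for hC4B/- vs WT, 4 for hC4A/A vs WT, 10 for hC4A/- vs C4-/-, 3 for hC4B/- vs C4-/-, 1 for hC4A/A vs C4-/- and for the allele trend, 58 for hC4A/- vs hC4B/-, 2 for hC4A/A vs hC4A/- and 9 for any difference among the 4 genotypes other than WT. Limma voom with quality weights called 6 for hC4A/- vs WT, 1142 for hC4B/- vs WT, 1 for hC4A/- vs C4-/- and 1930 for hC4A/- vs hC4B/-. It reversed the log2 fold change of Cd46 to 0.20 in hC4A/- vs C4-/- and 0.17 in hC4B/- vs C4-/-, and of Ifi204 to -0.19 in hC4A/- vs hC4B/-. RLE size factors gave 7 genes for any difference among the 4 genotypes. With no filter edgeR called 26 genes for C4-/- vs WT, 65 for hC4A/- vs WT, 28 for hC4B/- vs WT, 3 for hC4A/A vs WT, 53 for hC4A/- vs C4-/-, 16 for hC4B/- vs C4-/-, 36 for hC4A/- vs hC4B/- and 277 for any difference. With the genes of the deposited matrix the counts in that order were 37, 83, 48, 5, 72, 25, 64 and 211, and 57 list results passed in place of 20. Only the groups compared gave 1 gene for hC4A/- vs WT and 1 for hC4A/A vs WT, and 1 surrogate variable gave 1 for C4-/- vs WT and 1 for hC4A/- vs WT. With 1 surrogate variable C4b reversed to -0.68 in hC4B/- vs C4-/-, -0.092 in hC4A/A vs C4-/- and 0.57 in hC4A/- vs hC4B/-, and ribosomal proteins in hC4A/- vs hC4B/- reversed with an adjusted p of 0.00651. The stricter filter called 0 genes in every contrast. Number series as a factor, fitted on the 16 libraries other than WT, called 0 in each contrast without WT. It reversed Cd46 in hC4B/- vs C4-/- to 1.76.

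Without the 4 broad libraries edgeR called 1 gene for hC4A/- vs WT, Tubb5, and 10 list results passed. C4b then reversed to -2.35 in hC4B/- vs C4-/-, -1.51 in hC4A/A vs C4-/-, 1.32 in hC4A/- vs hC4B/- and -0.48 in hC4A/A vs hC4A/-. Other genes that reversed were Cep83 (-0.14), Fam117a (-3.33) and Mocs2 (-0.15) in hC4B/- vs C4-/-, Aloxe3 (3.00), Cbx7 (1.42) and Zmiz2 (0.87) in hC4A/- vs hC4B/-, and Aloxe3 (-2.31) and Jak3 (-1.38) in hC4B/- vs WT. Lists that reversed were homeostatic microglia in hC4A/A vs C4-/- (adjusted p = 0.851), ribosomal proteins in hC4A/- vs hC4B/- (0.856) and in hC4A/A vs WT (0.948), and oxidative phosphorylation in hC4A/A vs WT (0.966). The receptor covariate reversed C4b to -0.30 in hC4B/- vs C4-/-, -0.16 in hC4A/A vs C4-/-, 0.21 in hC4A/- vs hC4B/- and -0.058 in hC4A/A vs hC4A/-, and ribosomal proteins in hC4A/- vs hC4B/- (0.995). Camera with the estimated correlation passed 0 list results, directional fry 0 and mixed fry 3. The share of genes near C4b with an unadjusted p under 0.05 in hC4B/- vs WT gave a Fisher exact p of 0.0726 within 5 Mb and 5.1e-04 within 20 Mb, where hC4A/A vs WT (0.0071) and hC4A/- vs hC4B/- (0.028) were also under 0.05, none of them adjusted over contrasts.

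With the replicate number as a block, edgeR called 0 genes in every contrast, 19 list results passed in place of 20, and Ifi204 in hC4A/- vs hC4B/- reversed to -0.021. The numbers gave no clear sign of pairing the libraries. The median correlation of deviations was 0.0082 over 33 pairs of libraries with the same number and 7.7e-04 over 124 pairs with different numbers. Of the 33 pairs 5 were over 0.1, and of the 124 pairs 10 were. In all, 5 libraries correlated best with one of their own number, and the number that chance gives was not computed.

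Leaving out each library in turn gave 0 to 19 genes for any difference among the 4 genotypes other than WT (2 to 19 without WT replicates 2, 3 or 4, hC4A/A replicates 1 or 2 or hC4B/- replicates 1, 2 or 4), 0 to 8 for hC4A/- vs hC4B/-, 0 to 2 for hC4B/- vs WT and 0 to 1 for hC4A/A vs WT, and 10 to 27 list results, the 10 without hC4A/A replicate 2. Where that leaves 1 hC4A/A library, it is assumed to vary like the other groups. Log2 fold changes ran from -3.14 to 0.29 for Lpl and from -2.76 to 0.36 for Cd46 in hC4A/- vs C4-/-, from -0.24 to 6.25 for Mocs2 in hC4B/- vs C4-/-, from -0.014 to 4.96 for Lcn2 and from -2.46 to 3.10 for C4b in hC4A/A vs C4-/-, from -0.0095 to 2.87 for Ndufa10 and from -0.48 to 5.20 for C4b in hC4A/A vs hC4A/-, and from -0.18 to 3.02 for Rpl22 in hC4A/A vs WT. Adjusted p ran from 1.09e-05 to 0.913 for ribosomal proteins in hC4A/- vs hC4B/-. In hC4A/A vs C4-/- it ran from 0.00144 to 0.903 for homeostatic microglia, from 5.67e-08 to 0.903 for oxidative phosphorylation and from 1.84e-25 to 0.903 for ribosomal proteins. In hC4A/A vs WT it ran from 3.39e-06 to 0.943 for oxidative phosphorylation and from 6.82e-17 to 0.939 for ribosomal proteins.

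Other splits of the libraries cannot exclude chance for any count of genes, since the real count was 0. All 50 splits drawn gave as many for C4-/- vs WT, hC4A/- vs C4-/-, hC4B/- vs C4-/-, hC4A/- vs hC4B/-, hC4A/- vs WT and the 4 other genotypes vs WT, and so did all 35 for hC4B/- vs WT. The highest other count was 0, 1, 51, 4, 0 and 2410 in that order and 0 for hC4B/- vs WT, and splits with 51 and 2410 genes point to a structure of the libraries other than the labels. At an unadjusted p under 0.05, the real split was matched or passed by 10, 7, 28, 7, 23 and 22 of the 50 splits in that order and by 7 of the 35 for hC4B/- vs WT, so chance is not excluded for those counts either. In simulated data edgeR recovered at most 6% of 4-fold and at least 50% of 16-fold changes, and what limits this was not tested.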

Other observations

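The tests in this part were chosen only after the result was seen.

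Ccl2 and Tubb5 separated WT from the rest, with all 4 WT libraries above all 16 others. Together with Nfkbid, Sppl2a, Ywhab, Psat1, Nup98, Zfp318, Glod4, Rbm28, Gm44668, Gm2956 and Gm7805 they made 13 such genes, and C4b, Bcr, Rnf130, Diexf and Gm3435 made 5 with all WT libraries below. Of the 4845 choices of 4 libraries out of 20, 89 gave 13 or more genes above the rest (a share of 0.0184) and 480 gave 5 or more below (0.0991), and the highest other choice gave 1201 above. Without the broad libraries WT stood above in 14 genes (0.0841 of choices gave as many) and below in 13 (0.0907).

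Neutrophil markers were higher on average in WT than in each other genotype. The neutrophil score averaged 4.57 ± 1.61 in WT (SD, n = 4), 1.67 ± 1.33 in C4-/- (n = 5), 2.39 ± 1.28 in hC4A/- (n = 5), 2.54 ± 1.32 in hC4B/- (n = 4) and 3.18 ± 0.09 in hC4A/A (n = 2). The list has 10 genes, 8 of them tested and 0 in another list. Over the 12 libraries other than WT and the broad ones, the relation of the immediate early score to the neutrophil score did not pass (Pearson r = 0.185, permutation p = 0.554, Spearman rho = 0.301, p = 0.343, and adjusted over 2 relations 0.554 and 0.343), and r was 0.00122 without the 2 farthest libraries. The homeostatic score averaged 7.87 ± 0.38 in WT, 8.05 ± 0.36 in C4-/-, 7.74 ± 0.34 in hC4A/-, 7.83 ± 0.38 in hC4B/- and 7.57 ± 0.52 in hC4A/A.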
